A study of Mus musculus with 3 samples.

How the data were processed

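The data come from 3 libraries of single-cell combinatorial indexed ATAC-seq, an assay in which the transposase Tn5 inserts barcoded adapters into accessible chromatin, on nuclei of whole brain from C57BL6 mice. Per the labels' protocols, nuclei were freed from minced tissue by douncing and tagmented in 96 wells with well-specific barcodes. They were then pooled, washed and spread over a chip of 5184 nanowells, where the indexed PCR added the other barcode. The libraries carry the names sciATACv1, sciATACv2 and sciATACv3, shortened to v1, v2 and v3 below. What sets the versions apart, the number of nuclei and animals, and the sex and age of the animals are not given in the sources used here.

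The authors deposited 1 list of accessible regions (peaks) per library, with the chromosome, start and end of each peak and no score, height, read count or barcode. Per the submitters' processing notes, ArchR and MACS2 were used and the genome build is mm10; the aligner, tool versions, calling threshold and any excluded regions are not given in the sources used here. No peak was shorter than 500 bp, 500 bp was the most frequent width in each list, no peaks within a list overlapped or touched, and the lists covered chromosomes 1 to 19 and X. Sequencing depth per library is unknown, so the number of peaks cannot be set against it, and values per nucleus were not analysed here.

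Peak positions were set against a table of gene spans of the assembly GRCm38.p6, the same build as mm10, with 49554 genes on these chromosomes, of which 21631 are protein-coding. The table gives gene starts and ends without strand, exons or transcription start sites. The planned promoter, exon and intron classes were therefore replaced by the share of peaks with their midpoint inside a gene span, and the planned promoter peaks by peaks within 1 kb of either end of a protein-coding gene span, so an end may be the start or the end of transcription. Coordinates are 1-based.

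Overlap between libraries required at least 1 bp. The chance level came from 20 seeded random placements of the peaks within their chromosomes. Peaks of the 3 libraries were also merged into 1 set of regions, each counted by the libraries with a peak in it. A gene window was the gene span with 5 kb on each side. The share ratio of a gene between libraries was the ratio of its peaks as shares of all peaks of each library, with an exact conditional binomial 95% interval, and log2 share ratios used a pseudocount of 0.5 peaks (100 bp for covered length) scaled to each library's total. This scaling was adopted after the first list percentiles were seen, because an equal pseudocount gave genes without any peak a ratio other than 0; the equal pseudocount was kept as an alternative.

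Before the data were examined, 18 gene lists with 203 genes were fixed, and every gene was found in the table. They covered 12 brain cell types, immediate early genes, housekeeping genes and 4 other tissues. The median peaks per window of a list was placed among 10000 random lists of the same size matched on deciles of window length, and its median log2 share ratio among 10000 random lists matched on deciles of mean peak share. Percentiles above 97.5 or below 2.5 were called outside the random lists. Windows of neighbouring genes can overlap, so list members that lie close together may count the same peaks, while random lists were drawn without regard to position. After the first list percentiles had been seen, second lists of other marker genes were written for 5 of the cell types and set against random lists in the same way. The percentiles describe these libraries and are not tests between versions. The named genes followed a rule also fixed before: from each list the 2 genes with the most peaks averaged over the libraries and up to 2 members with no peak at an end in any library, and for each pair of libraries the 3 protein-coding genes with the largest log2 share ratio in each direction among genes with at least 30 peaks summed over the libraries. Some genes that the rule names are not reported here.

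Each version is represented by 1 library, so the spread between replicates is unknown, no test between versions was run and no p-value is given. Shares have exact Clopper-Pearson 95% intervals, and all intervals cover counting error only. On copies of the v1 list simulated with known changes over 21631 genes, 100 genes with doubled peaks gave a median log2 ratio of 0.93, 100 genes with halved peaks gave -1.12, and 4% of 200 unchanged lists fell outside the random lists. The changed genes and unchanged lists came only from genes above a minimum number of v1 peaks, and each gene's count was simulated independently. The 4% is thus no rate of false calls for lists whose genes have few or shared peaks. The alternatives tried were a reciprocal overlap of 50%, an equal number of peaks drawn from each library, protein-coding genes only, 500 bp around gene ends, gene spans alone, flanks of 20 kb and unmatched random lists. Covered length in place of peak number, peaks wider than 500 bp, chance by shifted chromosomes and the equal pseudocount were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.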

Results

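Chromatin accessibility was profiled in mouse whole brain with 3 versions of a nanowell-based single-cell ATAC-seq preparation, 1 library per version. The comparisons ask how the accessible regions found with each version resemble one another. The v2 library listed 850991 peaks, the v1 library 622754 and the v3 library 512023. The v2 library thus had 1.37 times the peaks of the v1 library, and the v3 library 0.822 times. Peaks of the v3 library were wider, with a median of 726 bp against 500 bp in the v1 and v2 libraries, and 42.2% of them had the minimum width of 500 bp against 59.8% in v1 and 53.1% in v2. Together the peaks covered 454 Mb in v1, 669 Mb in v2 and 490 Mb in v3, which is 17.7%, 26.0% and 19.1% of the chromosome spans. The widest peak of the v2 library spanned 7606 bp at chromosome 7, 101508021 to 101515626 (mm10), in Pde2a, a phosphodiesterase gene. The widest v3 peak spanned 7578 bp at chromosome 18, 35789933 to 35797510, over Ube2d2a, which encodes a ubiquitin-conjugating enzyme. The widest v1 peak, 7051 bp at chromosome 17, 39839904 to 39846954, overlapped no protein-coding gene span.

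The X chromosome was the chromosome with the fewest peaks per Mb in all 3 libraries. It held 73.3 peaks per Mb in the v1 library, 131 in v2 and 66.3 in v3, while the autosomes ranged from 190 to 284, 255 to 372 and 180 to 242. The share of peaks on X was 1.97% in v1, 2.59% in v2 and 2.17% in v3. Between v2 and v1 the X share had a ratio of 1.31, outside the 0.938 to 1.06 of the 19 autosomes. Between v3 and v1 the ratio was 1.10, inside the autosomal range of 0.886 to 1.17, and among peaks wider than 500 bp it was 1.18, above the highest autosome at 1.15. Between v3 and v2 it was 0.840, below the lowest autosome at 0.880.

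**Figure D1:**
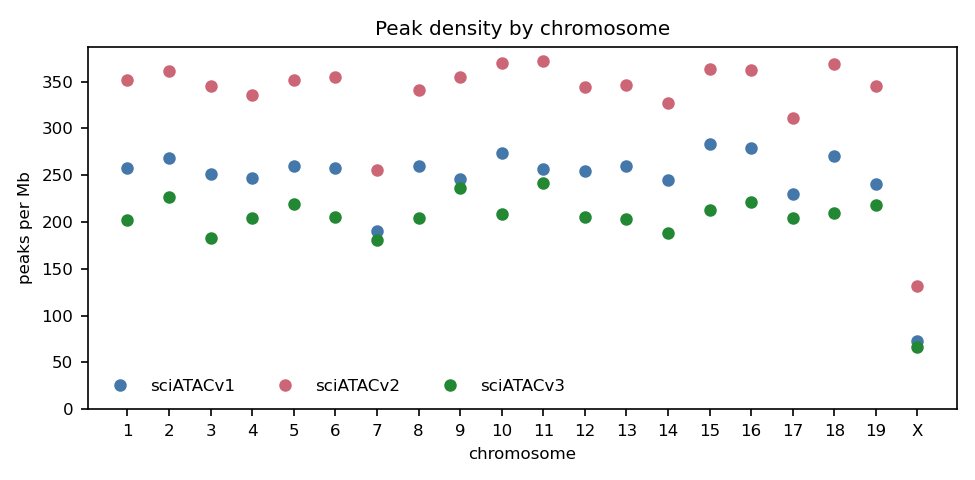
Peaks per Mb (vertical axis) on each chromosome (horizontal axis), 1 point per library. The X chromosome lies below every autosome in each library, at 73.3 (v1), 131 (v2) and 66.3 (v3) peaks per Mb.

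Most peaks of the v1 and v3 libraries were also present in the larger v2 list. Of the v1 peaks, 90.8% (95% interval 90.8 to 90.9) overlapped a v2 peak, against 43.4% for randomly placed peaks, and 70.7% overlapped a v3 peak, against 30.4%. Of the v3 peaks, 86.3% (86.2 to 86.4) overlapped a v2 peak and 75.2% (75.1 to 75.3) a v1 peak, against 46.2% and 34.1% by random placement. Of the v2 peaks, 64.5% overlapped a v1 peak and 58.7% a v3 peak, against 32.1% and 30.9%. Of the v2 peaks over 1500 bp, 94.6% were met in v3, against 43.8% of those of 500 bp, a contrast that arises in part because a wider peak is also met more often by chance. By bases, the overlap as a percentage of the union was 52.7% for v1 and v2, 48.2% for v1 and v3 and 46.1% for v2 and v3. With 512023 peaks drawn from each library, the share of v1 peaks met by v2 was 56.5% and that of v3 peaks met by v2 was 56.6%. Drawing fewer v2 peaks lowers these shares by itself. No random placements were made at equal numbers, so the drop does not show that the overlap with v2 comes from its size.

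**Figure D2:**
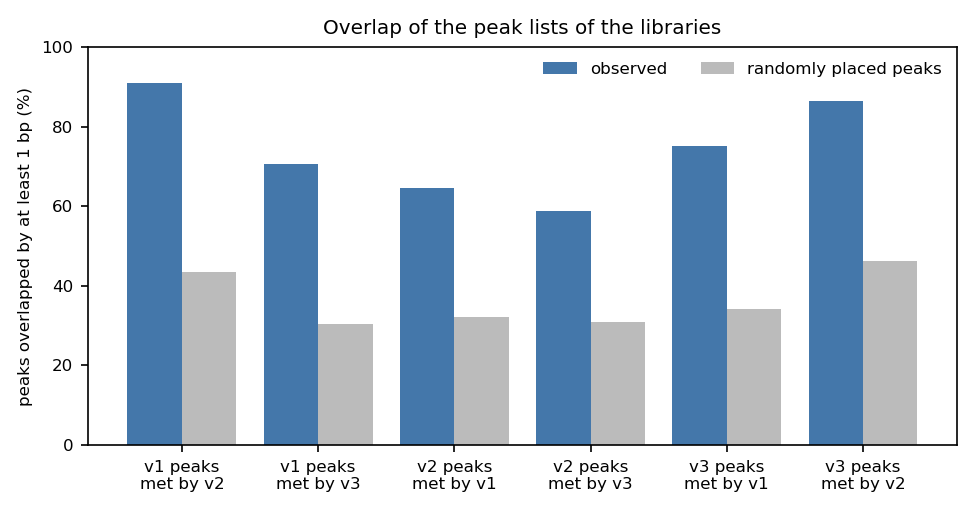
Percentage of the peaks of one library overlapped by at least 1 bp by a peak of another (blue) and the mean of 20 random placements (grey). Observed overlap ranges from 58.7% to 90.8% and random overlap from 30.4% to 46.2%.

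Regions with a peak in all 3 libraries lay in genes more often than regions of 1 library. Merging the lists gave 825280 regions, of which 322000 (39.0%) had a peak in all 3 libraries, 191380 (23.2%) in 2 and 311900 (37.8%) in 1. Of the regions present in all 3 libraries, 71.5% had their midpoint in a gene, against 53.2% of the regions of 1 library. Their median widths, 1366 and 500 bp, differ in part by construction, since a merged region spans all the peaks in it. Width and gene share go together: in v1, 72.0% of peaks wider than 500 bp lay in genes against 64.8% of those of 500 bp. The gene shares of the regions were not compared at equal width. Of the regions of 1 library, the v2 library held 215687, the v3 library 55869 and the v1 library 40344, with 52.3%, 62.5% and 45.4% in a gene. The v1 value lay under the 49.0% of all v1 peaks placed at random. With at least 50% of a region covered in each library, the share found in all 3 was 29.5%. With equal numbers of peaks it was 25.6%, a fall that drawing fewer peaks brings by itself.

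Peaks lay in genes more often than random positions in every library. The share of peaks with the midpoint in a gene span was 67.7% in v1 (95% interval 67.6 to 67.8), 64.6% in v2 (64.5 to 64.7) and 70.4% in v3 (70.3 to 70.5), against 49.0%, 49.0% and 49.2% for random placements. A peak lay within 1 kb of an end of 17530 of the 21631 protein-coding genes in v1 (81.0%), 18350 in v2 (84.8%) and 17439 in v3 (80.6%). Random placements reached 70.7%, 81.5% and 67.2% of genes, so the excess was smallest in v2. With 512023 peaks drawn from the v2 library, 73.4% of genes had a peak at an end.

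Genes of brain cell types carried peaks at their ends almost without exception. Of the 141 genes in the 12 brain cell type lists, 137 had a peak within 1 kb of an end in v1, 140 in v2 and 137 in v3, while random lists of the same window lengths had 111 to 127, 117 to 131 and 111 to 127. The microglial gene Aif1, which encodes the calcium-binding protein Iba1, had no peak at an end in any library, although its window held 4, 9 and 6 peaks in v1, v2 and v3. Of the 40 genes in the lists of lymphocytes, erythroid cells, hepatocytes and skeletal muscle, 29, 35 and 27 had such a peak, within the random ranges of 27 to 37, 29 to 38 and 27 to 37. The lists of other tissues differed from one another. All 10 skeletal muscle genes, among them the myosin heavy chain gene Myh1 and the actinin gene Actn3, had a peak at an end in each library, against 4, 6 and 4 of the 10 hepatocyte genes. Serpina1a, which encodes the liver-secreted protease inhibitor alpha-1 antitrypsin and has close copies nearby that can limit unique mapping, had 0 peaks in its window in all 3 libraries. Cyp2e1, a liver cytochrome P450 gene, had 2, 3 and 3 peaks and none at an end.

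In the number of peaks per gene window, the hepatocyte list lay below the random lists in every library, with medians of 2, 4 and 3 peaks in v1, v2 and v3 against random medians of 6.5, 9 and 6 (percentiles 0.33, 0.735 and 2.18). In the v1 library the cerebellar neuron list lay above the random lists, with a median of 12 peaks against 7 (percentile 99.4). In the v3 library the inhibitory neuron list (9 peaks against 6, percentile 97.7) and the ependymal and choroid plexus list (9 against 5, percentile 99.5) lay above them. These are levels within v3. In v3 over v1 the share ratios of these 2 lists lay inside the random lists, at percentiles 59.98 and 4.71. No list lay above the random lists in v2, where the astrocyte list came closest with 16 peaks against 12 (percentile 97.1). Long neuronal genes were among those with the most peaks. Erbb4, a neuregulin receptor gene of interneurons, had 441 peaks in v1, 403 in v2 and 224 in v3, and Foxp1, a transcription factor gene of striatal neurons, had 353, 419 and 280. Grin2b, which encodes an NMDA receptor subunit, had 292, 319 and 253. Pde10a, the phosphodiesterase gene of striatal neurons, had 260, 273 and 195, and Adarb2, an interneuron gene, had 266, 265 and 134. Glial genes followed with Lhfpl3 (178, 225 and 87 peaks), Gli3 (112, 160 and 65) and Slc1a2, the astrocytic glutamate transporter gene (85, 93 and 71). The myelin gene Mbp had 63, 85 and 56 peaks. All 3 lists above the random lists moved inside under 3 or more alternatives, the cerebellar list down to percentile 84.4 and the inhibitory and ependymal lists to 73.4 and 70.7, each with unmatched random lists. The hepatocyte list moved inside in v2 with 20 kb flanks (8.41) and equal numbers of peaks (3.66), and in v3 with 20 kb flanks (2.91), unmatched lists (4.56) and peaks wider than 500 bp (4.59).

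Gene windows ranked alike in the 3 libraries. Across 21631 protein-coding genes, which are not independent replicates, Spearman's correlation of peaks per window was 0.960 for v1 and v2, 0.953 for v1 and v3 and 0.953 for v2 and v3, and per bp of window it was 0.850, 0.841 and 0.811. The median log2 share ratio over the 9711 genes with at least 30 peaks was -0.09 for v2 over v1, 0.09 for v3 over v1 and 0.19 for v3 over v2, so each list is set against its own random lists. By chance 0.9 of the 18 lists would lie outside the random lists in a pair.

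Between v2 and v1, the fixed lists of cerebellar neuron, oligodendrocyte and inhibitory neuron genes held a lower share of peaks in the v2 library. Second lists of other genes of these cell types, chosen later, lay inside the random lists, at percentiles 8.53, 51.9 and 5.23. The cerebellar neuron list had a median log2 share ratio of -0.59 against -0.28 to 0.26 in random lists (percentile 0.01), with 11 of 12 genes lower, among them the transcription factor gene Etv1 (share ratio 0.719, 95% interval 0.492 to 1.05). The oligodendrocyte list had a median of -0.39 (percentile 0.22; 11 of 12 lower), although its 2 genes with the most peaks stood near equal shares, Mbp at 0.987 (0.704 to 1.39) and the transcription factor gene Myrf at 1.13 (0.643 to 2.03). The inhibitory neuron list had a median of -0.30 (percentile 1.58, 12 of 13 lower), with Erbb4 at 0.669 (0.583 to 0.767) and Adarb2 at 0.729 (0.613 to 0.868). These 2 genes were also lower in v3 than in v1, at 0.618 (0.524 to 0.727) and 0.613 (0.494 to 0.757). The list as a whole was not low in v3 over v1 (percentile 59.98, 8 of 13 higher), so the fall of these 2 genes is not particular to v2. The immediate early list had a median of -0.39 (percentile 1.54; 7 of 10 lower), but Nr4a1, at 1.24 (0.538 to 3.04), and Npas4, at 1.02 (0.423 to 2.58), were not among the lower genes. Above the random lists lay the lymphocyte list (0.54, percentile 97.9; 7 of 10 higher), with the T cell genes Cd4 and Lck at 1.39 (0.615 to 3.35) and 1.59 (0.562 to 5.09), and the hepatocyte list (0.70, percentile 99.8; 7 of 10 higher), whose genes hold few peaks.

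The single genes with the largest differences between v2 and v1 included Prox1, a homeobox transcription factor gene of dentate granule cells and lymphatic endothelium. Its window around chromosome 1, 190118035 to 190170827, held 38 peaks in v1, 16 in v2 and 14 in v3 (share ratio v2 over v1 0.308, 0.160 to 0.566). Slc17a6, the vesicular glutamate transporter gene VGLUT2, held 16, 8 and 13 peaks (0.366, 0.136 to 0.906), and the predicted gene LOC108168726 held 28, 15 and 12 (0.392, 0.195 to 0.759). In the other direction, the predicted gene Gm7133 held 3, 26 and 4 peaks (6.34, 1.94 to 32.7). The collagen VI gene Col6a2 held 4, 22 and 5 (4.02, 1.37 to 16.1). These genes are the extremes of 9711, so their ratios overstate what a repeat would show. The oligodendrocyte list moved inside the random lists with equal numbers of peaks (percentile 3.28), 20 kb flanks (5.55) and peaks wider than 500 bp (5.63), the inhibitory list with 20 kb flanks (4.74) and covered length (3.87), the immediate early list with covered length (13.1) and wider peaks (26.2), the lymphocyte list with 20 kb flanks (88.5), and the hepatocyte list with gene spans alone (89.1) and wider peaks (46.4). The fixed cerebellar list stayed below 2.5 in every alternative run.

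**Figure D3:**
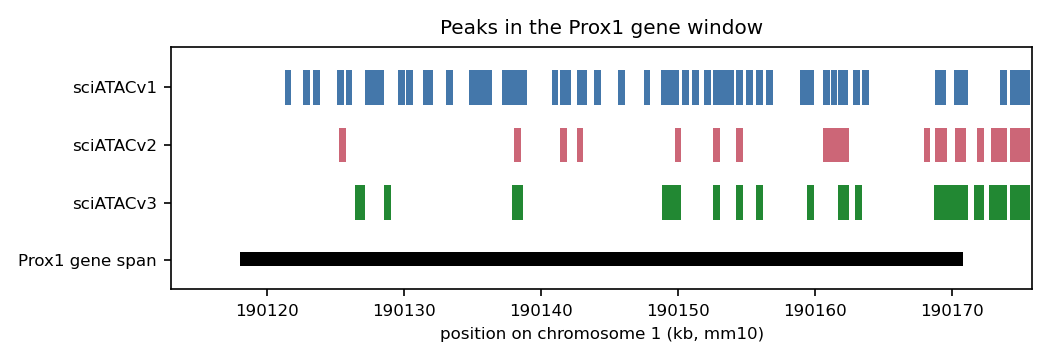
Peaks in the Prox1 gene window (chromosome 1, position in kb on mm10), 1 line of boxes per library, with the gene span in black. The v1 library lists 38 peaks, the v2 library 16 and the v3 library 14.

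Between v3 and v1, the fixed lists of microglial and endothelial genes held a higher share of peaks in the v3 library. Second lists of other genes of these cell types lay inside the random lists, at percentiles 96.6 and 54.5. The fixed microglia list had a median log2 share ratio of 0.68 against -0.15 to 0.40 in random lists (percentile 99.99; 12 of 14 genes higher). Its 2 genes with the most peaks did not stand out, P2ry12, a purinergic receptor gene, at a share ratio of 0.811 (0.463 to 1.40) and the transcription factor gene Spi1 at 1.15 (0.570 to 2.32). The complement genes C1qa, C1qb and C1qc, all among the higher genes, are not separate wherever their windows overlap and share peaks. The endothelial list had a median of 0.66 (percentile 99.95; 10 of 12 higher), with the VEGF receptor gene Flt1 at 2.37 (1.33 to 4.36) and the transcription factor gene Erg at 1.73 (1.16 to 2.59). The hepatocyte list also lay above (0.49, percentile 99.7), on 7 higher genes and 3 without any peak in either library. The mural and fibroblast list lay below the random lists (-0.34, percentile 0.24; 9 of 12 lower), with the pericyte channel gene Abcc9 at 0.669 (0.290 to 1.46) but Pdgfrb, the pericyte growth factor receptor gene, at 1.34 (0.697 to 2.58).

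Among single genes, Csnka2ip held 18, 19 and 1 peaks in v1, v2 and v3 (share ratio v3 over v1 0.0676, 0.00162 to 0.428). Tfec, a transcription factor gene, held 14, 19 and 1 (0.0869, 0.00205 to 0.571), and Slc30a8, the zinc transporter gene of pancreatic beta cells, held 21, 15 and 3 (0.174, 0.0332 to 0.582). Higher in v3 were Dcaf10, with 5, 16 and 21 peaks (5.11, 1.87 to 17.3), Psmb2, a proteasome subunit gene, with 5, 17 and 20 (4.87, 1.77 to 16.6), and Far1, a fatty acyl-CoA reductase gene, with 9, 23 and 33 (4.46, 2.09 to 10.6). These genes too are extremes of 9711, and the lower ones rest on 1 or 3 peaks in v3, so their ratios overstate what a repeat would show. With gene spans alone, the microglia list lay at percentile 48.2, although its number of peaks in v3 was then above the random lists (98.2), and the mural list at 11.4 and the hepatocyte list at 85.3 moved inside too. Among peaks wider than 500 bp the mural list lay at 19.9, the hepatocyte list at 96.2 and the endothelial list at 94.98; the endothelial list also moved inside with covered length (96.2), and the hepatocyte list with 20 kb flanks (96.5) and equal numbers of peaks (95.3). Below the random lists under some alternatives only lay the striatal list (0.68 with 20 kb flanks, 0.26 with covered length), the cerebellar list (0.07 with 20 kb flanks, 2.46 unmatched, 0.705 among wider peaks), the oligodendrocyte list (1.92 with covered length, 1.33 among wider peaks) and the immediate early list (0.56 among wider peaks).

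Between v3 and v2, the fixed microglia and endothelial lists again held a higher share in the v3 library, which is the same v3 library as above and so not independent. The second lists lay inside the random lists, at percentiles 93.3 for microglia and 52.4 for endothelial cells. The fixed microglia list had a median log2 share ratio of 0.60 (percentile 99.96; 11 of 14 higher) and the endothelial list 0.60 (percentile 99.9; 11 of 12 higher), with Flt1 at a share ratio of 1.76 (1.08 to 2.87). The excitatory neuron list had a median of 0.42 (percentile 98.2; 11 of 13 higher), with Grin2b at 1.32 (1.11 to 1.56). The erythroid list lay below the random lists at -0.85 (percentile 0.035; 8 of 10 lower). Its anion exchanger gene Slc4a1 held 9, 15 and 1 peaks (v3 over v2 0.111, 0.00263 to 0.720). The lymphocyte list lay below as well (-0.51, percentile 1.98; 7 of 10 lower).

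Csnka2ip and Tfec had the lowest single-gene ratios of v3 over v2 too, both at 0.0875 (0.00211 to 0.550), followed by the signalling gene Wnt2 with 13, 33 and 3 peaks (0.151, 0.0296 to 0.482). The highest were the predicted gene Gm21154 with 11, 6 and 13 peaks (3.60, 1.28 to 11.6), Suz12, a Polycomb repressive complex gene, with 8, 11 and 23 (3.48, 1.63 to 7.90), and Chordc1 with 9, 9 and 18 (3.32, 1.42 to 8.40). Chosen as extremes by the same rule, these genes also have ratios that overstate what a repeat would show. The microglia list lay at percentile 69.1 with gene spans alone, the endothelial list at 97.3 with 20 kb flanks, the erythroid list at 44.4 among peaks wider than 500 bp, and the excitatory list at 94.0 with gene spans alone, 94.1 with equal numbers of peaks and 86.9 among wider peaks. The lymphocyte list lay at 24.965 with 20 kb flanks, 26.2 with equal numbers of peaks, 2.8 with covered length and 2.52 with the equal pseudocount, which also put the inhibitory list outside (97.6 in place of 95.4).

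**Figure D4:**
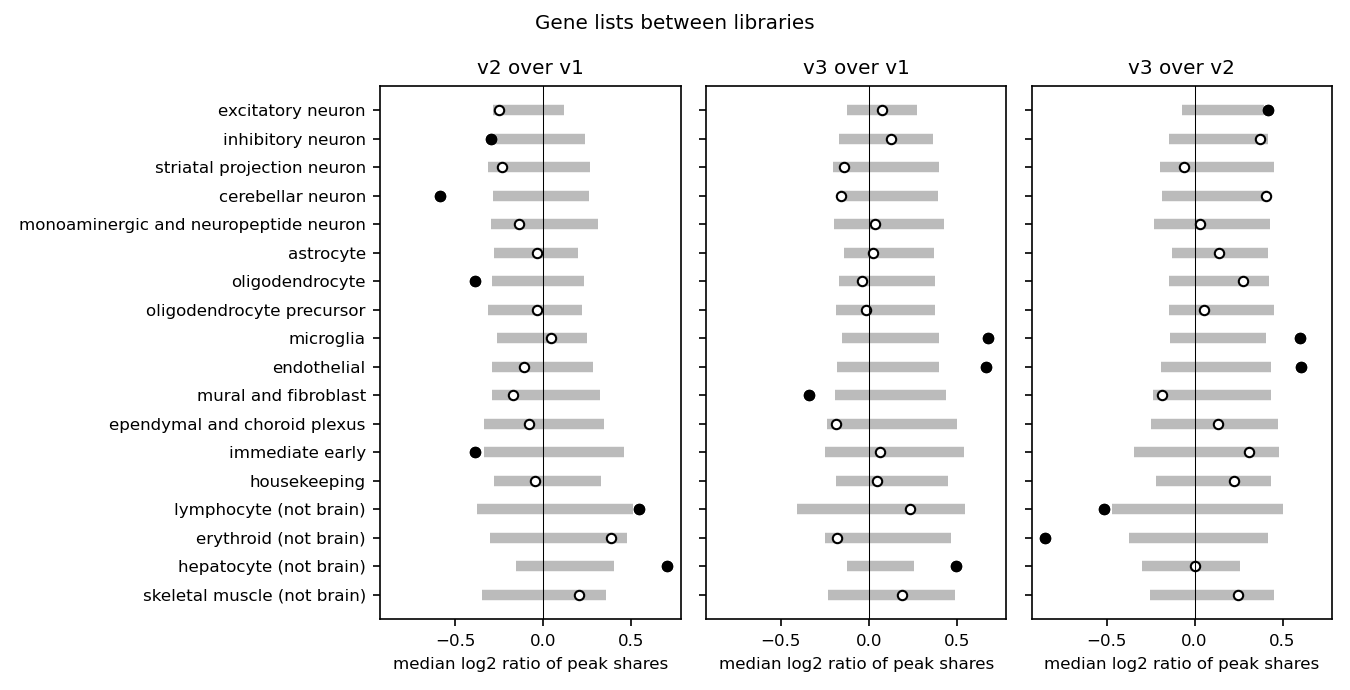
Median log2 ratio of peak shares of each gene list (horizontal axis) for the 3 pairs of libraries, with grey bars for the central 95% range of 10000 matched random lists and filled points for lists outside it. The microglia list lies at 0.68 for v3 over v1 and the cerebellar neuron list at -0.59 for v2 over v1.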

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

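Covered length, peaks wider than 500 bp and the equal pseudocount were chosen after seeing the data; the cause of the shifts was not tested except where peaks were removed. Of 324 list percentiles under alternatives, 290 stayed on their side of the limits, 16 lost and 18 gained a call. Of 378 list ratio percentiles, 330 stayed, 27 lost and 19 gained a call. Another 2 lost a call and moved to slightly under the middle of the random lists, microglia in v3 over v1 with gene spans alone (48.175) and hepatocyte in v2 over v1 among peaks wider than 500 bp (46.36). All 90 values for the named genes of the pairs kept their direction and lay within the counting interval. These genes were picked as extremes of the same peaks and many of their intervals are wide, so this says little about stability. Calls gained in v2 over v1 were microglia (99.89 with covered length, 99.7 among wider peaks), mural (1.22 with 20 kb flanks), erythroid (98.5 unmatched) and skeletal muscle (98.5 with gene spans alone). In v3 over v2 they were inhibitory neuron (99.6 among wider peaks), striatal (0.08 with 20 kb flanks), cerebellar (98.0 with gene spans alone, 97.7 unmatched) and immediate early (97.9 with covered length). The equal pseudocount changed 2 of the 54 list calls, inhibitory neuron (97.625) and lymphocyte (2.52) in v3 over v2. Peaks wider than 500 bp numbered 250407 in v1, 398801 in v2 and 296094 in v3, so v3 then exceeded v1. With reciprocal overlap of 50%, v2 met 68.8% of v1 peaks, v1 met 52.5% of v3 peaks and v2 met 59.5% of v3 peaks; with equal numbers these were 56.5%, 64.1% and 56.6%, and among wider peaks 87.4%, 62.3% and 78.2%. Regions in all 3 libraries made up 29.5% with 50% coverage, 25.6% with equal numbers and 36.5% among wider peaks. Drawing equal numbers lowers overlap by removing peaks alone. In v1, v2 and v3, 61.1%, 57.6% and 63.9% of peaks lay in protein-coding genes, and 72.0%, 68.7% and 72.0% of wider peaks lay in genes. Genes with a peak at an end made up 77.7%, 82.5% and 77.7% within 500 bp and 72.9%, 79.1% and 76.4% for wider peaks; with equal numbers they made up 76.4% in v1 and 73.4% in v2. Lists above the random lists in v1 numbered 3 with gene spans alone, 0 with 20 kb flanks, 0 unmatched, 2 with covered length and 4 among wider peaks. In v2 there was 1 with gene spans alone, 1 with equal numbers and 1 with covered length, and in v3 there was 1 with 20 kb flanks, 0 unmatched and 1 among wider peaks. Lists outside in v3 over v1 numbered 1 with gene spans alone, and in v3 over v2 numbered 3 with equal numbers. Rank correlations with 20 kb flanks, equal numbers, covered length and wider peaks were 0.955, 0.932, 0.970 and 0.938 for v2 over v1, 0.945, 0.945, 0.967 and 0.933 for v3 over v1, and 0.945, 0.933, 0.966 and 0.944 for v3 over v2. Not run were the highest-scoring peaks (the lists carry no score), the wider promoter window and values per nucleus; merging touching peaks, autosomes and X only, and peaks of at least 300 bp remove nothing here and say nothing about stability. Without known depth, peak number and sensitivity of calling cannot be separated.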

Other observations

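Gene families with known tissue ranges, chosen after the data were seen, differed widely in accessibility. Of 1110 olfactory receptor genes, which act in the nasal epithelium, 15.6% had a peak within 1 kb of an end in v1, 22.4% in v2 and 13.2% in v3, and 63.8%, 52.9% and 71.0% had no peak in their window. Of 353 vomeronasal receptor genes, 6.23%, 7.37% and 2.83% had a peak at an end, and 75.1%, 73.9% and 89.5% had none in the window; their close copies can limit unique mapping. The 53 keratin genes, typical of epithelia, had medians of 2, 5 and 3 peaks, at percentiles 0, 3.5 and 5.13 of random lists matched on window length. All 40 proteasome subunit genes, used in every cell, had a peak at an end in each library.

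The 39 Hox genes, which pattern the body axis, had medians of 7, 8 and 7 peaks per window against 4, 5 and 3 in random lists (percentiles 100, 99.9 and 100). The 57 clustered protocadherin genes, adhesion genes of neurons, had medians of 42, 56 and 45 against 20, 30 and 18 (percentiles 99.97, 99.99 and 100). Windows of neighbouring genes overlap in these clusters, so the genes of a cluster share peaks and the percentiles overstate the evidence.

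For the patterns below, the tests of merging by covered length, of X among peaks wider than 500 bp and of Xist were chosen after the result was seen. The others were written before their own result. The second lists and the peaks wider than 500 bp were still taken up after the data had been seen. The switch to the scaled pseudocount also came after these tests had been seen once, and it changed the reading of 1 of them, named below. Version, animals and mix of nuclei are confounded in every pattern, since each version is 1 library. Peaks wider than 500 bp leave out the peaks of minimum width. The lists carry no score or height, so width is not known to follow strength and weak peaks were not tested as such.

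The X chromosome held a share of peaks 1.31 times higher in v2 than in v1. Autosomal 1 Mb bins matched on v3 peaks reached 1.07 at the upper end of their central 95% range, so the matched autosomal bins did not show this shift. The smallest pool to draw from held 9 of the 2470 autosomal bins, so the range may be too narrow. Copy number in these bins does not differ by sex, so they cannot tell whether more sensitive calling reached more of an X with fewer copies. More permissive calling therefore stays open for X, whose share rose in the order v1, v3, v2, as did covered length (454, 490 and 669 Mb). Peaks wider than 500 bp rose in that order too (250407, 296094 and 398801). The number of all peaks did not, since it rose in the order v3, v1, v2 (512023, 622754 and 850991). The X ratio of v2 over v1 was also 1.31 among peaks wider than 500 bp, which argues against a difference in peaks of minimum width alone. Animals of different sex, with fewer X copies in v1, remain a candidate explanation: Xist, the RNA gene of X inactivation at chromosome X, 103460373 to 103483233, had 4, 14 and 11 peaks in its window in v1, v2 and v3, and its v2 over v1 ratio lay at percentile 98.7 of 4843 genes with a similar number of peaks. Among 101 X-linked genes it lay only at percentile 93.1, and its share ratio of 2.56 has a counting interval of 0.804 to 10.7. In v3 over v1 the Xist share ratio was 3.34 (0.991 to 14.4), at percentile 99.5 of all these genes and 99.01 of the X-linked ones. In v3 over v2 it was 1.31 (0.536 to 3.10), at percentiles 71.4 and 73.8. Both pairs go with fewer X copies in v1 alone, but these intervals include equal shares and Xist is 1 gene. By covered length the Xist window held 2347, 9786 and 10834 bp in v1, v2 and v3. A peak crossed the upper end of the Xist span in v2 (103482628 to 103483839) and v3 (103482622 to 103484705) but not in v1. The nearest v1 peak lay at 103484067 to 103484566. The gene table has no strand, so it does not tell whether this end is the start of transcription. The v3 over v1 ratio of X, 1.10, lay above autosomal bins matched on v2 peaks (0.784 to 0.917) but inside the range of whole autosomes (0.886 to 1.17). The smallest pool of matching bins held only 4 here, so this matched range may be too narrow as well. In v3 over v2, where fewer X copies in v1 alone predict no difference, X lay below the lowest autosome (0.840 against 0.880). Among wider peaks it was 0.900 against 0.906. No matched bins were drawn for v3 over v2, and in v3 over v1 the matched bins had a median of only 0.851. The comparison with whole autosomes thus cannot decide against sex, which stays open. The labels name no sex and the lists hold no Y peaks.

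The fixed microglia and endothelial lists held a higher share of peaks in v3 than in v1. For microglia, merging of neighbouring peaks and peaks of minimum width are argued against as the whole cause, since the list lay at percentile 99.99 with covered length and at 100 among peaks wider than 500 bp. A second list of 14 other microglial genes lay at 96.6, just short of the upper limit, so the choice of genes cannot be told apart from a wider microglial difference. For endothelial genes a second list lay at 54.5, which fits a pattern tied to the chosen genes, and covered length (96.2) and wider peaks (94.98) leave merging and peaks of minimum width open. A different share of microglial nuclei may contribute: a low v1 alone would not put the fixed list above the random lists in v3 over v2 (99.96 by peak number, 98.9 with covered length, 99.02 among wider peaks), nor a high v3 alone in v2 over v1 (99.89 with covered length and 99.7 among wider peaks, but 69.8 by peak number), while gene spans alone (48.2 in v3 over v1, 69.1 in v3 over v2) and the second list in v3 over v2 (93.3) lay inside.

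The fixed cerebellar, oligodendrocyte and inhibitory neuron lists held a lower share of peaks in v2 than in v1. For cerebellar genes, merging (percentile 0 with covered length) and peaks of minimum width (0.01 among wider peaks) are argued against, while a second list lay at 8.53 and leaves the choice of genes open. In v3 over v1 the second list lay at 1.96 and the fixed list at 2.65, so other cerebellar genes were also low relative to v1 there. That pair shares the v1 library and so is not independent. In v3 over v2 the lists lay apart, the fixed list at 96.9 and the second list at 6.51. For oligodendrocyte genes the second list lay at 51.9, which fits a pattern tied to the chosen genes. Covered length gave 0.1, against merging, and wider peaks gave 5.63, which leaves peaks of minimum width open. For inhibitory genes, wider peaks gave 0.5, against peaks of minimum width alone. Covered length (3.87) and the second list (5.23) leave merging and gene choice open. With the equal pseudocount covered length gave 2.38, which would have argued against merging. Dissection that left out part of the cerebellum may lower the cerebellar list alone, which was not tested here.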
